A study of Homo sapiens with 9 samples.

How the data were processed

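The analysis started from the raw counts per gene in the 2 tables that the authors deposited. According to the submitters' notes, the authors trimmed reads with fastp, aligned them with HISAT2 to hg38 and counted them per gene with featureCounts. Versions, strand settings and the handling of reads with more than 1 placement are not given in the sources used here, and neither is the conversion method. Columns were matched to samples by their names. Each table held 59235 genes that could be read. In each, 16 genes had broken lines and were left out. The 3 control FdiA libraries were identical in both tables over all 59235 genes and were used once in each comparison, so the 2 comparisons share them.

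Fits of the 2 groups of each comparison were made in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM factors, glmQLFit and glmQLFTest. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. CPM values were normalized within each comparison, and log2 CPM used a prior count of 2. Levels of the same control FdiA libraries therefore differ between the comparisons. Over that group, 3 counts correspond to 0.0214 CPM in the first comparison and 0.0165 CPM in the second. SLC1A3, for example, was at 61.7 ± 2.78 and 47.5 ± 2.19 CPM in control FdiA. CPM values should thus be compared only within a comparison. Gene lists, 27 in all, were fixed before the data were examined: astrocyte, fibroblast and collagen matrix, neuron, oligodendrocyte, microglia, neural progenitor, pluripotency, smooth muscle, adipocyte, endothelial, epithelial, and melanocyte and Schwann cell markers; cell division, cholesterol synthesis, glycolysis, unfolded protein response and mitochondrially encoded genes; A1, A2 and pan-reactive genes; and NF-kB, cytokine, interferon, MHC class I, MHC class II, complement and matrix protease genes. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, which is printed beside each list that passed with TMM and all libraries. List p-values were adjusted over the lists of the comparison. Some genes stand on several lists, so list results are not independent of one another.

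Genes were named by a rule fixed at the same time. It took the 5 highest and 5 lowest log2 fold changes past the threshold among protein-coding genes with at least 10 CPM in the higher group and no overlap between groups. It added up to 4 members per list with the largest absolute change past the threshold, or the 2 most abundant where none passed. It also added 2 panels given whatever their result. The conversion panel was GFAP, S100B, AQP4, ALDH1L1, SLC1A2, SLC1A3, SOX9, NFIA, GJA1, VIM, COL1A1, COL1A2, THY1, S100A4, TUBB3 and MKI67. The stimulation panel was GFAP, IL6, CXCL8, CCL2, CXCL10, C3, ICAM1, VCAM1, LCN2, SERPINA3, GBP2, SERPING1, SLC1A3, PTX3 and SOD2. Genes that would tell the sex of a donor are not shown. Some genes that the rule picked are not reported here.

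A group without counts was set to 3 counts over the group, and the fold is then given as at least that size. Such folds rest on that floor and are not absolute minima. Groups with 1 to 3 counts got a ratio with a 95% counting interval. These intervals and floors cover counting error only, since the libraries carry no molecular identifiers that are described in the sources used here. Replicates differed by more than counting error, with a chi-square per degree of freedom of 9.32 to 53.8 between pairs. Gene positions and biotypes came from RefSeq on hg38, where 5149 genes also have a model on an alternate, fix or random contig. There were 580 ribosomal RNA genes, some inside the larger RNA45SN1, so a read can enter more than 1 of them. That group was defined to include RNR1 and RNR2, the mitochondrial ribosomal RNAs. The ribosomal RNA shares below are therefore not split into nuclear and mitochondrial. KRT18 and other genes with related copies share reads in unknown proportion.

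Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no low-count filter, at least 10 CPM in 3 libraries, a replicate block, each library left out in turn, a 2-fold minimum, an adjusted p under 0.01, and all 9 libraries in a single fit. Leaving out ribosomal RNA genes, with TMM or with library totals alone, was added after seeing the data. The scripts were tested on simulated data with 50 changed genes per effect size, 200 per comparison. That is far fewer than the real data gave, so the rates below belong to the simulated setting only. At a log2 fold change of 1 they called 72% in both comparisons, at 0.5 they called 36% and 32%, and 3.87% and 7.50% of calls among simulated genes were false.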

Results

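Messenger RNA was measured by bulk RNA sequencing in 9 libraries of cultured human cells, in 3 groups of 3. The starting cells were adult fibroblast cultures grown with 15% fetal bovine serum. The FdiA groups (fibroblast-derived induced astrocytes, cells converted directly from fibroblasts) were labelled D40 and kept in astrocyte maturation medium. One FdiA group was left unstimulated (control FdiA), and the other received interleukin-1 beta, TNF-alpha and complement C1q for 24 hours (stimulated FdiA). All libraries came from 1 donor line, and the labels do not say whether replicates were separate cultures. Total counts per library were 46169682, 38397789 and 51357435 for fibroblasts, 53785814, 44706345 and 58829712 for control FdiA, and 63646397, 46197557 and 50450096 for stimulated FdiA. Ribosomal RNA genes held 34.0 ± 5.93% of counts in fibroblasts, 37.3 ± 4.85% in control FdiA and 45.7 ± 0.981% in stimulated FdiA (mean ± SD, n = 3). Outside those genes, the 13 mitochondrially encoded mRNAs held 3.96 ± 0.836%, 4.22 ± 0.827% and 6.63 ± 0.291% of counts. Gene levels below are normalized CPM (counts scaled to library size after TMM), as mean ± SD with n = 3 libraries per group, and genome positions are on hg38. The p-values measure only the spread between these libraries.

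The first comparison, control FdiA against fibroblasts, asked how far the converted cells had taken on astrocyte expression. The astrocyte glutamate transporter SLC1A3 (chromosome 5, 36606606 to 36688334) was 44.9-fold higher in control FdiA, rising from 1.39 ± 0.292 to 61.7 ± 2.78 CPM. The astrocyte filament gene GFAP (chromosome 17, 44903159 to 44915500) rose 2.71-fold but stayed at 1.71 ± 0.486 CPM, and the water channel AQP4 had no counts in any of the 6 libraries. All 18 tested cell division genes fell, with the proliferation marker MKI67 (chromosome 10, 128096659 to 128126423) 48.9-fold lower. Matrix genes moved both ways, with the proteoglycan DCN 17.9-fold higher and the collagen COL1A1 2.64-fold lower; elastin (ELN), picked after its values were seen, fell from 1141 ± 92.6 to 0.440 ± 0.189 CPM. Of 21 tested cytokine and chemokine genes, 19 were higher in control FdiA, which had not received the stimulating cytokines. The composition of their medium is not given in the sources used here.

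Of 17885 genes tested, 5659 were higher and 5688 lower in control FdiA (adjusted p under 0.05), together 63.4%. Changes of at least 2-fold covered 2935 higher and 2467 lower genes. The libraries of the 2 groups did not overlap for 68.2% of tested genes, where chance gives 10%. Scaling by library totals alone, without TMM factors, moved the median of all genes to -0.32 on the log2 scale and gave 3404 higher and 7227 lower genes. Of 26 gene lists that could be tested as a set, 11 passed with the preset correlation of the camera test. With an estimated correlation 0 of them passed camera, and 4 lists had an unadjusted p under 0.05. Member counts adjusted over the list alone were the same as those over all genes, apart from the 3 lists where both are given.

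Among 30 astrocyte markers, 18 were tested, of which 13 rose and 3 fell, with a median log2 fold change of 1.76. The list passed (adjusted p = 0.00228, and adjusted p = 0.168 with an estimated correlation). APOE, the main lipid carrier of astrocytes, rose from 1.14 ± 0.404 to 20.1 ± 3.96 CPM. The gap junction gene GJA1 rose from 57.6 ± 4.78 to 586.6 ± 6.17 CPM. The glial transcription factors NFIA and SOX9 reached 19.2 ± 1.15 and 7.06 ± 1.26 CPM, changes of 3.96-fold and 2.91-fold. NDRG2 rose 15.8-fold and the angiotensin precursor AGT rose from 0.326 ± 0.106 CPM, but they ended at 5.35 ± 0.625 and 4.34 ± 1.01 CPM. The second glutamate transporter SLC1A2 rose 2.38-fold to 7.27 ± 1.36 CPM. CLU, SLC4A4 and FGFR3 fell. These 3, like other list members below that the naming rule did not pick, were chosen after their values were seen. Several classical markers stayed at the limit of detection. S100B had 0 counts in fibroblasts and 3 in control FdiA, and ALDH1L1 had 1 and 0. Over a group, 3 counts correspond to 0.0197 CPM in fibroblasts and 0.0214 CPM in control FdiA. That is the floor used here for a count of 0, not the highest level it allows, and it covers counting error only.

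**Figure D1:**
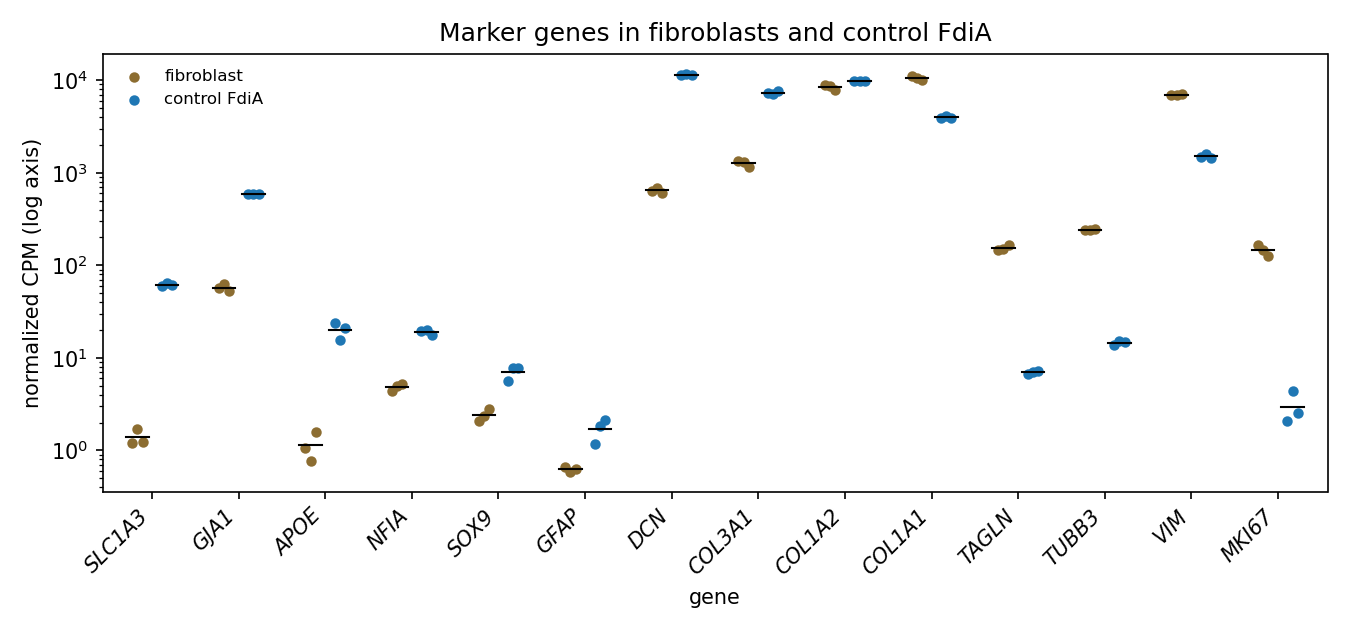
Normalized CPM (log axis) of 14 marker genes in the 3 fibroblast and 3 control FdiA libraries; each point is a library and each line a group mean. SLC1A3, GJA1, APOE and DCN sit more than 10-fold higher in control FdiA. TAGLN, TUBB3 and MKI67 sit more than 10-fold lower, and GFAP stays under 3 CPM.

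Of 28 fibroblast and collagen matrix genes, 16 rose and 10 fell (adjusted p = 0.0727). DCN reached 11513 ± 187 CPM from 643.9 ± 39.4, and FBLN1 rose 14.3-fold. COL3A1 rose from 1269 ± 107 to 7346 ± 335 CPM, while COL1A1 fell from 10564 ± 611 to 4006 ± 127 CPM. COL1A2 was at 8429 ± 558 and 9756 ± 66.2 CPM and did not pass (adjusted p = 0.0840). It passed as higher with DESeq2 (adjusted p = 0.0034), without the low-count filter (0.0409), without fibroblast replicate 1 (0.0378) and without ribosomal RNA genes (0.0157). The fibroblast surface and cytoplasmic markers THY1 and S100A4 fell by 0.41 and 0.46 on the log2 scale. With library totals alone 13 rose and 10 fell, and the list passed (adjusted p = 0.0375; with TMM, adjusted p = 0.645 with an estimated correlation). Smooth muscle and myofibroblast genes fell in 9 of 11 cases and rose in 1, CALD1, a list with adjusted p = 0.00268 and adjusted p = 0.304 with an estimated correlation. The actin-binding gene TPM1 fell from 566 ± 11.9 to 14.9 ± 1.27 CPM and TAGLN was 22.1-fold lower. The intermediate filament gene VIM fell 4.65-fold, from 6997 ± 140 to 1505 ± 82.3 CPM.

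Cytokine and chemokine genes had a median log2 fold change of 6.87 with 2 genes at their lower bound (19 of 21 higher, 2 lower, CSF1 and IL32; adjusted p = 1.82e-09, and adjusted p = 0.056 with an estimated correlation). The neutrophil-attracting CXCL5 rose from 0.977 ± 0.0618 to 1164 ± 72.5 CPM, the granulocyte growth factor CSF3 from 0.0278 ± 0.0156 to 90.1 ± 3.59 CPM, and CCL7 from 0.0596 ± 0.0559 to 93.3 ± 3.82 CPM. NF-kB targets rose in 15 of 20 cases and fell in 1, CYLD, or in 2 adjusted over the list alone (adjusted p = 0.000411, and adjusted p = 0.168 with an estimated correlation), and with library totals alone 13 rose and 3 fell. SOD2, which detoxifies superoxide in mitochondria, rose from 40.8 ± 2.35 to 1247 ± 27.9 CPM, and the adhesion genes ICAM1 and VCAM1 rose 11.9-fold and 60.6-fold. VCAM1 stayed low in control FdiA, at 1.63 ± 0.285 CPM with the scaling of the second comparison. Complement genes rose in 11 of 16 cases and fell in 4 (adjusted p = 0.0116, and adjusted p = 0.373 with an estimated correlation). The central component C3 (chromosome 19, 6677704 to 6720650) rose from 2.55 ± 0.377 to 265.5 ± 18.2 CPM. Among the 4 that fell were C4A and C4B, near-identical genes between which reads can be misassigned.

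Matrix metalloproteinase and ADAMTS genes, which break down matrix, rose in 11 of 13 cases and fell in 1, ADAMTS1 (adjusted p = 0.000133, and adjusted p = 0.373 with an estimated correlation). The collagenase MMP1 rose from 144.9 ± 12.1 to 9341 ± 906 CPM and the aggrecanase ADAMTS5 from 22.4 ± 2.65 to 322.8 ± 10.1 CPM. Interferon-stimulated genes rose in 16 of 27 cases and fell in 4 (adjusted p = 0.0267, and adjusted p = 0.645 with an estimated correlation), with OAS1 up 24.0-fold and IFI6 up 6.17-fold. That call was lost without fibroblast replicate 1 (adjusted p = 0.0501), without control FdiA replicate 3 (adjusted p = 0.0538) and with the stricter filter (adjusted p = 0.455).

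All 18 cell division genes fell, with a median log2 fold change of -5.32 (adjusted p = 3.57e-10, and adjusted p = 0.304 with an estimated correlation). The mitotic checkpoint genes CDC20 and BUB1 were 166.6-fold and 85.7-fold lower, and MKI67 fell from 145.3 ± 20.9 to 2.98 ± 1.19 CPM. Glycolysis genes fell in 14 of 15 cases and rose in 1, PFKM (adjusted p = 0.000381, and adjusted p = 0.304 with an estimated correlation), with PFKP 9.56-fold and ENO1 3.33-fold lower. Cholesterol synthesis genes rose in 17 of 21 cases and fell in 3, MVK, PMVK and EBP (adjusted p = 0.00228, and adjusted p = 0.550 with an estimated correlation), and with library totals alone 11 rose and 4 fell. MSMO1 rose from 27.6 ± 2.30 to 93.9 ± 4.64 CPM.

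Markers of other cell types split. Epithelial markers fell in 5 of 5 tested cases (median -7.12, adjusted p = 0.00228, and adjusted p = 0.168 with an estimated correlation). KRT19 had 6746 counts in fibroblasts and 3 in control FdiA, a 2074-fold ratio with a 95% counting interval of 709.5 to 10060, and KRT14 was at least 223-fold lower. Neuron markers rose in 6 of 13 cases and fell in 2, TUBB3 and MAP2 (adjusted p = 0.294). The synaptic vesicle release gene SNAP25 reached 5.83 ± 0.535 CPM from 0.0287 ± 0.0322 and SYT1 rose 17.3-fold, while the neuronal tubulin TUBB3 fell from 243.6 ± 3.20 to 14.7 ± 0.879 CPM. Oligodendrocyte lineage markers rose in 4 of 6 tested cases and fell in 1, CSPG4 (adjusted p = 0.219). The other 8 members were not tested, and MOG, MOBP, OLIG1 and OLIG2 had no counts in either group. Neural progenitor markers rose in 4 of 7 cases and fell in 2, or rose in 5 adjusted over the list alone (adjusted p = 0.207). Adipocyte markers rose in 2 of 3 cases, CEBPA and PPARG (adjusted p = 0.128, adjusted p = 0.594 with an estimated correlation, and 0.0375 with library totals alone). Endothelial markers rose in 2 of 6 cases and fell in 3 (adjusted p = 0.844). Microglia and macrophage markers rose in 1 of 4 tested cases, TMEM119, and fell in 2, CSF1R and CD14 (adjusted p = 0.581). The other 10 members were not tested, and AIF1, TYROBP, C1QA, C1QB and C1QC had no counts in either group. Of 2 pluripotency markers tested, SALL4 rose to 0.750 ± 0.130 CPM, too few members for a list test.

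The remaining lists did not pass. Reactive astrocyte genes named A1 rose in 4 of 8 cases and fell in 2 (adjusted p = 0.622), those named A2 rose in 3 of 11 and fell in 6 (adjusted p = 0.358), and pan-reactive genes rose in 5 of 9 and fell in 3 (adjusted p = 0.350). Genes of the unfolded protein and amino acid stress responses rose in 9 of 15 cases and fell in 4, or rose in 10 adjusted over the list alone (adjusted p = 0.177), and with library totals alone 4 rose and 4 fell. MHC class I presentation genes rose in 8 of 13 cases and fell in 1, NLRC5 (adjusted p = 0.143), with a median log2 fold change of 0.29 that turned to -0.03 with library totals alone, where 3 rose. Mitochondrially encoded genes rose in 6 of 13 cases (adjusted p = 0.164, and 0.0336 without control FdiA replicate 3). Their median of 0.30 turned to -0.02 with library totals alone, where 3 rose and 1 fell. The A1 median of 0.18 turned to -0.15 with that scaling, against a mean of -0.02 and an upward test. MHC class II genes rose in 1 of 5 cases, HLA-DPA1 (adjusted p = 0.925), with a median of -0.04, a mean of 0.24 and an upward test. For the A2 list the median was -0.49, the mean 0.15 and the test downward. Melanocyte and Schwann cell markers rose in 1 of 6 cases and fell in 2 (adjusted p = 0.581). Their median was 0.31, or -0.00 with library totals alone, their mean -0.68 and their test downward. The member that rose, MITF, lost its call without fibroblast replicate 3 (adjusted p = 0.0601) or control FdiA replicate 2 (adjusted p = 0.0529), and with library totals alone (adjusted p = 0.0812).

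Genes were also ranked by the fitted log2 fold change among those above 10 CPM, which puts genes with a group at 0 counts first, so their order is not an order of the bounds given here. The highest were CCL8 (at least 3073-fold), the collagen COL6A5 (at least 1519-fold), CCL11 (at least 912-fold), the prohormone convertase PCSK2 (3 counts in fibroblasts, ratio 7840 with a 95% counting interval of 2682 to 38020) and the growth factor EREG (at least 771-fold). The lowest were PI16 (at least 1890-fold), the cardiac actin ACTC1 (at least 1643-fold), KRTAP1-5 (at least 913-fold), KRT34 (at least 804-fold) and the cartilage proteoglycan ACAN (at least 681-fold). Some genes with counts in both groups, such as KRT19 and CSF3, changed by more than several of these bounds. The bounds set a group without counts at 3 counts over the group. KRTAP1-5 and KRT34 also have copies on alternate contigs, so their reads can be placed in more than 1 way. Medium, serum and conversion differed together between the groups and cannot be told apart here.

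The second comparison, stimulated against control FdiA, asked how the converted cells answered inflammatory cytokines. The neutrophil chemokine CXCL8 (chromosome 4, 73740569 to 73743716) rose 24.3-fold, from 356.7 ± 32.8 to 8669 ± 789 CPM, and the cytokine IL6 (chromosome 7, 22727200 to 22731998) rose 21.5-fold, from 61.3 ± 8.91 to 1319 ± 104 CPM. All 20 NF-kB targets rose. The collagens COL3A1 and COL1A1 were 3.74-fold and 3.23-fold lower, and the astrocyte transporter SLC1A3 fell 2.22-fold. GFAP was at 1.32 ± 0.370 and 2.01 ± 0.454 CPM and did not pass (adjusted p = 0.157).

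Of 17270 genes tested, 2288 were higher and 2157 lower in stimulated FdiA, together 25.7%. Changes of at least 2-fold covered 694 higher and 638 lower genes. The groups did not overlap for 40.4% of tested genes, where chance gives 10%. The balance depended on scaling. Library totals alone moved the median of all genes to -0.45 and gave 807 higher and 8149 lower genes. With ribosomal RNA genes also left out, a setting chosen after seeing the data, the median was -0.24 and the counts were 1218 and 5142. Of 25 lists tested, 11 passed with the preset correlation and 2 with an estimated one. Member counts adjusted over the list alone were the same as those over all genes, apart from the 5 lists where both are given.

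Cytokine and chemokine genes rose in 24 of 27 cases, or in 25 adjusted over the list alone, with a median log2 fold change of 3.19 with 3 genes at their lower bound (adjusted p = 8.30e-26, and adjusted p = 0.0192 with an estimated correlation). With library totals alone 23 rose and 2 fell. The dendritic cell and T cell attractant CCL20 rose from 0.756 ± 0.136 to 345.6 ± 20.9 CPM. CSF2 went from 2 counts to 2283 over the group, a ratio of 1514 with a 95% counting interval of 418.6 to 12510. CCL3 was at least 217-fold higher, though it has close paralogs and copies on alternate contigs, and TNF was at least 42.0-fold higher at 0.692 ± 0.224 CPM. CCL2, which attracts monocytes, rose 7.10-fold to 1158 ± 53.7 CPM. CXCL10 rose from 0.112 ± 0.121 to 0.667 ± 0.263 CPM, a call lost without control FdiA replicate 1 (adjusted p = 0.0776), control FdiA replicate 2 (adjusted p = 0.0819) or stimulated FdiA replicate 2 (adjusted p = 0.0895).

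The 20 NF-kB targets rose with every scaling tried, with a median log2 fold change of 1.60 (adjusted p = 3.81e-20, and adjusted p = 0.0192 with an estimated correlation). The survival genes BCL2A1 and BIRC3 rose 19.3-fold and 16.1-fold, and the feedback inhibitor TNFAIP3 rose from 23.7 ± 0.801 to 142.2 ± 7.91 CPM. SOD2 rose 4.17-fold to 4005 ± 85.9 CPM, ICAM1 rose 5.44-fold to 112.4 ± 5.28 CPM, and VCAM1 rose 4.94-fold to 8.05 ± 0.717 CPM. Matrix metalloproteinase and ADAMTS genes rose in 9 of 14 cases and fell in 1, ADAMTS1 (adjusted p = 1.61e-05, and adjusted p = 0.359 with an estimated correlation), and with library totals alone 9 rose and 5 fell. The elastase MMP12 rose from 34.6 ± 7.23 to 1147 ± 287 CPM and the stromelysin MMP3 from 2349 ± 411 to 18936 ± 3975 CPM.

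**Figure D2:**
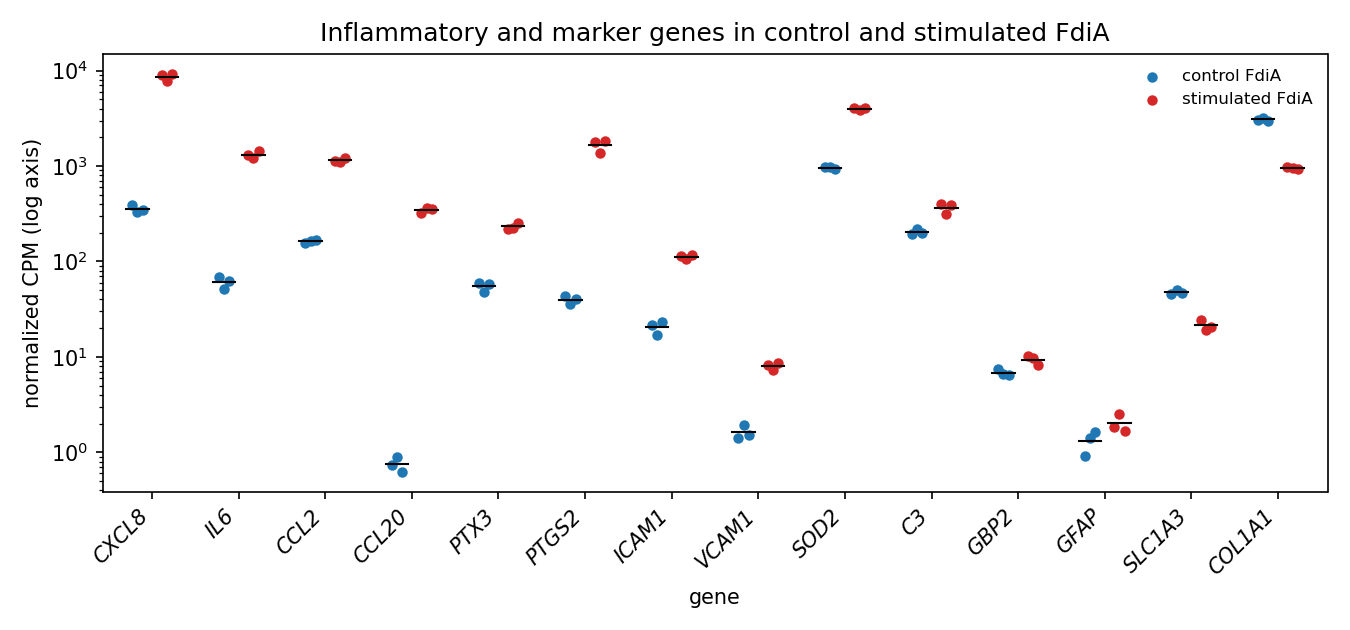
Normalized CPM (log axis) of 14 inflammatory and marker genes in the 3 control and 3 stimulated FdiA libraries; each point is a library and each line a group mean. CXCL8, IL6, CCL20 and PTGS2 sit more than 10-fold higher after stimulation, COL1A1 and SLC1A3 sit lower, and GFAP stays under 3 CPM.

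MHC class I presentation genes rose in 12 of 13 cases (adjusted p = 3.13e-08, and adjusted p = 0.169 with an estimated correlation), and 6 rose with library totals alone. The immunoproteasome subunits PSMB10 and PSMB9 rose 3.12-fold and 2.59-fold, and HLA-F rose 3.85-fold; the HLA genes are similar to one another and have alternate haplotype contigs. A1 reactive astrocyte genes rose in 6 of 8 cases and fell in 1, FKBP5 (adjusted p = 0.00749, and adjusted p = 0.169 with an estimated correlation). This list shares HLA-E and PSMB8 with the MHC class I list. The adhesion gene AMIGO2 rose 12.3-fold, from 0.415 ± 0.112 to 5.09 ± 0.287 CPM, and SRGN rose 5.86-fold. GBP2 rose from 6.84 ± 0.609 to 9.38 ± 1.01 CPM, a call lost without control FdiA replicate 2 (adjusted p = 0.0658), control FdiA replicate 3 (adjusted p = 0.0815) or stimulated FdiA replicate 1 (adjusted p = 0.0565), and with library totals alone (adjusted p = 0.956). FKBP5 lost its call without control FdiA replicate 2 (adjusted p = 0.0790), control FdiA replicate 3 (adjusted p = 0.0616) or stimulated FdiA replicate 3 (adjusted p = 0.0515). The complement inhibitor SERPING1 was at 72.5 ± 1.89 and 69.1 ± 6.41 CPM (adjusted p = 0.619), and it passed as lower with library totals alone (-0.52, adjusted p = 0.000623). With library totals alone 2 A1 genes rose and 2 fell. A2 genes rose in 7 of 11 cases and fell in 1, CD109 (adjusted p = 0.000336, and adjusted p = 0.169 with an estimated correlation), and with library totals alone 6 rose and 3 fell. PTGS2, the inducible enzyme of prostaglandin synthesis, rose 41.8-fold to 1662 ± 265 CPM and the pattern recognition protein PTX3 4.22-fold to 232.9 ± 19.2 CPM.

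All 13 mitochondrially encoded mRNAs rose, with a median log2 fold change of 0.89 (adjusted p = 4.41e-07, and adjusted p = 0.359 with an estimated correlation), and with library totals alone all 13 rose by a median of 0.43. COX1 went from 7758 ± 1598 to 14534 ± 886 CPM. Cholesterol synthesis genes rose in 14 of 21 cases, or in 16 adjusted over the list alone (adjusted p = 3.66e-05, and adjusted p = 0.359 with an estimated correlation), but with library totals alone 2 rose and 3 fell and their median turned from 0.36 to -0.08. INSIG1 rose 2.17-fold. Unfolded protein and amino acid stress genes rose in 9 of 15 cases and fell in 1, PSAT1 (adjusted p = 0.00132, and adjusted p = 0.169 with an estimated correlation), and their median turned from 0.28 to -0.16 with library totals alone, where 2 rose and 3 fell. The stress transcription factor ATF3 rose 4.92-fold and CHAC1, which degrades glutathione, 3.50-fold.

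Fibroblast and collagen matrix genes fell in 16 of 28 cases and rose in 1, SNAI2 (adjusted p = 5.33e-07, and adjusted p = 0.169 with an estimated correlation), and with library totals alone 27 fell and 0 rose in edgeR. COL3A1 fell from 5657 ± 239 to 1513 ± 118 CPM and COL1A1 from 3085 ± 104 to 955.7 ± 23.1 CPM. The microfibril gene FBN1 and the collagen COL5A1 fell 3.18-fold and 3.08-fold. Oligodendrocyte lineage markers fell in 5 of 6 tested cases (adjusted p = 0.00386, and adjusted p = 0.169 with an estimated correlation). MBP went down from 5.03 ± 0.440 to 1.64 ± 0.127 CPM. The other 8 members were not tested, and MOG, MAG, MOBP, OLIG1 and OLIG2 had no counts in either group. Astrocyte markers fell in 6 of 18 cases and rose in 3 (adjusted p = 0.214), and with library totals alone 11 fell and 1 rose. SLC1A3 fell from 47.5 ± 2.19 to 21.4 ± 2.59 CPM, and NFIA and NDRG2 fell 2.49-fold and 2.37-fold. The bicarbonate transporter SLC4A4 rose 2.31-fold.

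**Figure D3:**
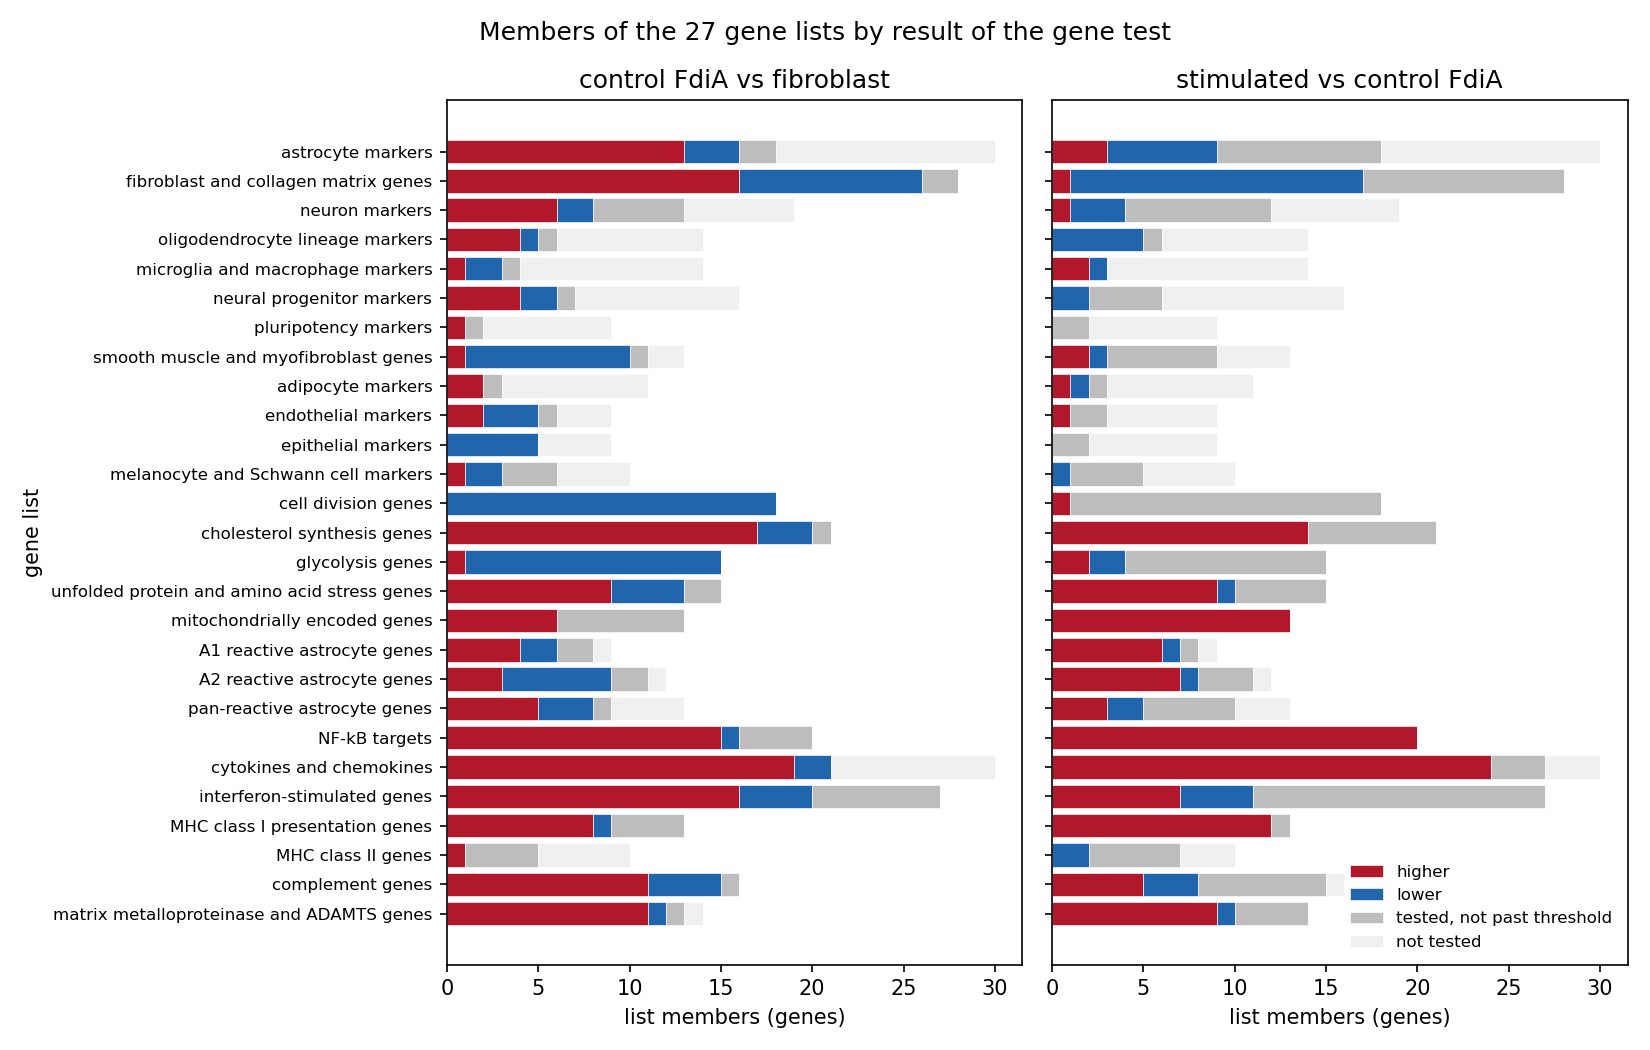
Members of the 27 gene lists (number of genes) by result of the gene test in both comparisons; each bar is a list, split into genes that were higher, lower, tested but not past the threshold, or not tested. In stimulated FdiA all 20 NF-kB targets and all 13 mitochondrially encoded genes were higher, and in control FdiA all 18 cell division genes were lower, with library totals alone as well. Under that scaling the higher cholesterol synthesis genes of stimulated FdiA went from 14 to 2.

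The other lists did not pass. Interferon-stimulated genes rose in 7 of 27 cases and fell in 4 (adjusted p = 0.270, and 0.0337 without stimulated FdiA replicate 2), and their median turned from 0.14 to -0.30 with library totals alone, where 2 rose and 10 fell. OASL rose 2.73-fold and IFIT1 fell 2.23-fold. Complement genes rose in 5 of 15 cases and fell in 3 (adjusted p = 0.575), with a median of -0.01, a mean of 0.13 and an upward test. With library totals alone 3 rose and 7 fell, and the median was -0.46. CFB rose 4.10-fold and C3 1.80-fold, to 367.3 ± 47.0 CPM. Pan-reactive genes rose in 3 of 10 cases and fell in 2 (adjusted p = 0.227), and their median turned from 0.28 to -0.17 with library totals alone, where 2 rose and 4 fell. TIMP1 rose 2.41-fold, and STEAP4 fell 13.2-fold, from 1.32 ± 0.332 to 0.0915 ± 0.100 CPM. LCN2 had no counts in these 6 libraries, and SERPINA3 was at 0.0264 ± 0.0325 and 0.128 ± 0.141 CPM, too low to be tested. MHC class II genes fell in 2 of 7 cases (adjusted p = 0.599). Those were HLA-DPA1, whose call was lost without control FdiA replicate 2 (adjusted p = 0.0641) or control FdiA replicate 3 (adjusted p = 0.0748) and with all 9 libraries in a single fit (adjusted p = 0.0557), and HLA-DMA, whose call was lost without any of 4 libraries (adjusted p up to 0.256 without control FdiA replicate 2). Neuron markers rose in 1 of 12 cases and fell in 3, or rose in 3 and fell in 3 adjusted over the list alone (adjusted p = 0.469), with a median of -0.24 and a mean of 0.00.

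Neural progenitor markers fell in 2 of 6 cases, NES and HES1, or in 3 adjusted over the list alone (adjusted p = 0.194). Microglia and macrophage markers rose in 2 of 3 tested cases, CD14 and CD68, and fell in 1, TMEM119 (adjusted p = 0.227). The other 11 members were not tested, and AIF1, TYROBP, C1QA, C1QB and C1QC had no counts in either group. Melanocyte and Schwann cell markers fell in 1 of 5 cases, PMP22 (adjusted p = 0.212). Adipocyte markers split, with PPARG down 1.92-fold and CEBPA up 1.30-fold (adjusted p = 0.490); CEBPA turned to -0.07 with library totals alone and was not called without control FdiA replicate 1 or 3 (adjusted p = 0.134 and 0.137) or stimulated FdiA replicate 2 (adjusted p = 0.116), or with all 9 libraries in a single fit (adjusted p = 0.0560). Endothelial markers rose in 1 of 3 cases, KDR (adjusted p = 0.103), and their median turned from 0.34 to -0.11 with library totals alone. Smooth muscle genes rose in 2 of 9 cases, TPM1 and CNN1, and fell in 1, ACTA2 (adjusted p = 0.469), and their median turned from 0.18 to -0.26 with that scaling. CNN1 lost its call without any of 4 libraries (adjusted p up to 0.268 without stimulated FdiA replicate 2), with library totals alone (0.189) and with a replicate block (0.0603). Cell division genes rose in 1 of 18 cases, UBE2C, or in 0 adjusted over the list alone (adjusted p = 0.263, and 0.0444 without control FdiA replicate 2), and their median turned from 0.23 to -0.24 with library totals alone, where 0 rose and 5 fell. UBE2C was not called without any of 4 libraries (adjusted p up to 0.0958 without stimulated FdiA replicate 2) or with library totals alone (0.0883). Glycolysis genes rose in 2 of 15 cases, HK1 and ALDOA, and fell in 2, PFKM and LDHA (adjusted p = 0.383), and their median turned from 0.08 to -0.36 with library totals alone, where 0 rose and 8 fell. Each of the 4 lost its call when 1 library was left out, and HK1 and ALDOA turned to -0.10 and -0.15 with library totals alone; LDHA lost it without any of 5 (adjusted p up to 0.135 without control FdiA replicate 3) and with a replicate block (0.0576). Pluripotency and epithelial markers had 2 tested members each, none past the threshold, so no list test was made.

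In the same ranking by fitted log2 fold change, the highest genes were the protease inhibitor SERPINB4 (at least 1049-fold; its paralog SERPINB3 is nearly identical), CSF2, CCL20 (457.9-fold), SERPINB7 (381.8-fold) and the interleukin subunit IL23A (307.9-fold, to 154.5 ± 22.0 CPM). The lowest were the protease ADAMTS15 (20.5-fold), the relaxin receptor RXFP1 (13.1-fold), the alcohol dehydrogenase ADH1B (from 74.3 ± 6.42 to 5.69 ± 0.912 CPM), RCAN2 (11.8-fold) and the potassium channel subunit KCNE4 (11.4-fold). Counts without any 1 library ranged from 3330 to 4728 changed genes, and the share of ribosomal RNA counts differed between the groups.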

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

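Against fibroblasts, 11347 changed genes became 10631 with library totals alone (3404 higher), 11136 with DESeq2, 11055 with a replicate block, 6746 with the stricter filter (3379 higher, 3367 lower), and 5402 with a 2-fold minimum (2935 higher, 2467 lower). The stricter filter tests fewer genes and the 2-fold minimum drops smaller changes by construction. After stimulation, 4445 became 8956 with library totals alone (807 higher, 8149 lower), 4650 with DESeq2, 4090 with a replicate block, and 1332 with a 2-fold minimum (694 higher, 638 lower). The stricter filter left 2969 (1539 higher, 1430 lower), and an adjusted p under 0.01 left 2898, of which 1369 were lower. With ribosomal RNA genes left out and library totals alone, a setting chosen after seeing the data, 1218 were higher and 5142 lower. Library totals alone leave out the TMM factors, which moves the genes of a comparison in the same direction by similar amounts.

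The replicate block, which pairs libraries by number, kept 11 lists in each comparison. With an estimated correlation, 0 camera lists passed against fibroblasts and 2 after stimulation; the preset correlation gave 11 each. Named genes that reversed after stimulation with library totals alone were CEBPA (-0.071), HK1 (-0.10) and ALDOA (-0.15). Leaving out 1 library gave 10743 to 11088 changed genes against fibroblasts and 3330 to 4728 after stimulation, and the cause of these differences was not tested. At log2 fold changes of 0.5, 36% and 32% of simulated changes were called. The simulations changed 200 genes per comparison, far fewer than were called here, so these rates do not carry over to the real comparisons.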

Other observations

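The metallothionein and HOX groups below, and the tests for leukocytes and for carried-over RNA, were chosen after the results were seen. Metallothioneins, small proteins that bind zinc and copper, rose together in stimulated FdiA. All 8 tested members rose, with a median log2 fold change of 3.73, and all 8 rose with library totals alone. MT2A rose from 655 ± 75.7 to 4903 ± 196 CPM and MT1E from 42.5 ± 6.82 to 413.8 ± 33.6 CPM (mean ± SD, n = 3). The MT1 genes are similar enough that reads can be placed on the wrong copy. Against fibroblasts, 5 of 7 tested members rose.

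HOX genes keep a record of the body position from which a fibroblast came. Of 30 tested HOX genes, 20 did not pass between fibroblasts and control FdiA, 6 rose and 4 fell, and 24 were within 2-fold. Levels were low, with a median over all 39 HOX genes of 2.37 CPM in fibroblasts and 2.56 CPM in control FdiA. The highest in control FdiA was at 19.5 CPM, so modest changes can have been missed. With library totals alone 4 rose and 8 fell, and their median turned from 0.05 to -0.28.

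In unstimulated FdiA 19 of 21 cytokine and chemokine genes and 15 of 20 NF-kB targets were higher than in fibroblasts, and 2 and 1 were lower (adjusted p = 0.056 and 0.168 with an estimated correlation). Leukocytes in the cultures were unlikely to be the source, since 12 leukocyte transcripts had a median of 0.098 CPM in control FdiA and 0.359 CPM in fibroblasts; of 7 tested, 2 rose (CD37 and HCLS1, to 0.505 and 1.62 CPM) and 3 fell, among them RAC2, the highest at 9.25 CPM. RNA carried over from stimulated libraries was also unlikely, since control FdiA held a median of 14.1% of the stimulated level over 19 such genes, while CCL20 bounds carry-over at 0.259%. With library totals alone, 32 of 34 members called higher stayed higher. Medium and serum differed together with conversion and were not tested.

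All 13 mitochondrially encoded mRNAs rose after stimulation, and with library totals alone 13 still rose, with a median of 0.43. A general gain of mitochondria would likely raise the nuclear subunits of the respiratory chain as well. These had a median log2 fold change of 0.15 (SE 0.0295 between genes, 75 genes), and -0.30 with library totals alone. That SE treats the genes as independent, although all were measured in the same libraries. As a list they shifted up with camera p = 0.0148, and p = 0.596 with an estimated correlation. Reads per cell were not measured, so a change in the amount of other RNA stays open.

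Against fibroblasts 9 of 11 smooth muscle genes fell, as did ID1 (from 311 ± 14.4 to 3.13 ± 1.43 CPM) and ID3, while SST, PCSK1 and NR4A2 rose, a pattern picked after the values were seen. Fibroblast and collagen matrix genes did not fall as a set, since 16 of 28 rose and 10 fell. Lower TGF-beta and BMP signalling in FdiA predicted that other targets would fall, and 13 of 16 did (camera p = 0.00172, and p = 0.173 with an estimated correlation). Higher cAMP signalling predicted that other targets would rise, and 12 of 14 did (camera p = 0.000438, and p = 0.0224 with an estimated correlation). Among all 17885 tested genes, 5688 were lower and 5659 higher. The feedback inhibitor SMAD7 fell by 1.82 on the log2 scale and the secretory granule gene SCG2 rose from 0.544 to 80.7 CPM, while PMEPA1, TGIF1 and COMP rose and PENK and VGF fell. Both are hypotheses: neither pathway was measured directly, and a role of the maturation medium, whose composition is not given in the sources used here, stays open and untested.

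All overlap counts here also needed an adjusted p under 0.05 in each comparison. Among the 16789 genes tested in both comparisons, 585 were at least 2-fold higher after stimulation. Of these, 214 were also at least 2-fold higher in control FdiA than in fibroblasts, where 102.3 would be expected if the comparisons were independent. Another 142 were at least 2-fold lower there, where 66.2 would be expected, so the excess was not confined to genes already higher. Without the 2-fold minimum, 821 genes were higher in both comparisons, where 734.5 would be expected. By the same count, 869 were higher after stimulation but lower in control FdiA than in fibroblasts, where 664.8 would be expected. Of the 633 at least 2-fold lower after stimulation, 395 were at least 2-fold higher in control FdiA than in fibroblasts and 62 lower. If the comparisons were independent, 110.7 and 71.7 would be expected. The 2 comparisons share the control FdiA libraries, which alone could give a negative covariance between them. Independence is therefore not a proper reference for these overlaps, and overlap counts without change were not simulated. The covariance was -0.21, taken over 18595 genes with all 9 libraries normalized together. For the same genes, 100 simulations without change gave a mean of -0.05 and a lowest of -0.06, so simulated noise gave part of it and left -0.16. A negative covariance is opposite to the rise of genes already higher, so this test does not bear on that overlap.

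The 6 libraries of each comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many changed genes in edgeR, 11347 and 4445, and the highest of the others was 0. At an unadjusted p under 0.05 the other splits gave 61 to 108 genes against 11841, and 219 to 446 against 6226. Every other split mixed libraries of both groups, so a difference between the groups widened the spread within its sides. Few calls could come from such splits, so they are no reference for chance and nothing is concluded from them.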
